A study of Mus musculus with 19 samples.

How the data were processed

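Liver RNA-seq values of 19 mouse samples were analysed in 4 groups taken from the sample titles: NC sham (n = 5), NC RIC (n = 5), CDAHFD sham (n = 5) and CDAHFD RIC (n = 4). RNA was extracted with Trizol and libraries were made with a VAHTS kit, per the labels. Whether the libraries keep strand was not given in the sources used here, so overlapping genes on opposite strands are uncertain. FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.1, HTSeq 0.13.5, DESeq2 1.18.1, R 3.4.1 and the mm10 assembly are named, without role or order, per the submitters' processing notes. The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the sample) with 1 column per sample. The program that made the FPKM and the gene annotation behind it were not given in the sources used here. Neither batches nor harvest times nor feeding state were given there.

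The table had 55335 entries. The 3225 without a gene name held 0.137% to 0.188% of the FPKM by group mean and were left out, which left 52110. Spreadsheet dates stood in place of the symbol for 26 of these (13 tested), and 160 shared a symbol with another entry (28 tested). Both kinds were tested and none of the date entries was named. Values of FPKM do not sum to the same total in each sample, and the authors' values were used as deposited. Because FPKM are not counts, no count model was used. Values were taken as log2(FPKM + 1), with a pseudocount of 1, and genes with a mean FPKM of at least 1 over the 19 samples were kept (10577). Differences on this scale understate the change of genes near the pseudocount. Positions came from the GENCODE gene annotation of the same assembly by symbol; 91.8% of the named entries (47824) had a match.

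Depth was estimated from low values. In single-exon genes FPKM times length is a whole multiple of what 1 read is worth. The most common value in each sample was taken as 1 read, which gave 15.9 to 26.4 M reads (mean 19.7 M). Of the low values, 27.1% to 32.2% lay within 2% of a whole number of reads, against 12.6% for a uniform spread, so reads were not recovered for most genes and the depth is an estimate. The 63 to 131 genes at the most common value count as whole by that choice, so part of the excess was fixed in advance. No pair of samples was a duplicate: at most 0.00945% of tested genes had the same value above 0 in both samples of a pair.

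Each comparison used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) with 1 mean per group over all 19 samples, 15 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene passed at an adjusted p under 0.05. The comparisons were CDAHFD sham minus NC sham, CDAHFD RIC minus CDAHFD sham, NC RIC minus NC sham, CDAHFD RIC minus NC RIC, and the interaction, the second of these minus the third. Gene lists (39 fixed) were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, which left 33, with adjustment over these lists within each comparison. Camera was repeated with an estimated correlation. Lists of B cell, T and NK cell, neutrophil, adipose, pancreas and skeletal muscle markers had fewer than 5 tested members and gave no test. A list's score in a sample is the mean of its members' log2(FPKM + 1) after each gene was centred on its mean over all samples. Scores were compared with two-sided exact permutation tests. Tables were handled with the data.table package (1.17.8), python 3.11.15 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

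The groups, the tests, the gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took, for the diet comparison in sham mice and for RIC on each diet, the 8 genes with the largest rise and the 8 with the largest fall among those that passed with no overlap between the groups, leaving out predicted genes and pseudogenes. It added up to 4 members with the smallest p of each list that passed, the 10 smallest p of the interaction, and a fixed set of genes. Of the 58 largest or smallest-p genes 57 are named, counting a gene once per comparison. Of 159 list members that the rule gave, 47 are named, and of 99 fixed genes 63. These subsets, and 16 further genes, were chosen after their values were seen. Values of 2 genes are not reported here. Both stay in the tests of the 39 fixed lists, and 1 was taken out of the feeding list, which left every printed score test unchanged.

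The script was tested on simulated data made from the real means and spreads with changes put into 200 genes. These were drawn only from genes with a mean log2(FPKM + 1) above 3. A further 20 genes were raised by 0.5 and counted as truly changed. Noise was drawn independently for each gene. The recovered shares thus do not cover lower genes, and neither they nor the false shares cover noise that is correlated between genes. At a log2 change of 1, 91% of changed genes were recovered for CDAHFD in sham mice, 94% for RIC on CDAHFD and 98.5% for RIC on NC, and at 0.5 the shares were 70.1%, 64.2% and 62.7%. Of the calls, 4.59%, 3.72% and 5.53% were false. Alternatives tried were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, rescaling to a common sum, median-ratio scaling, quantile normalization, fits of only the groups compared, robust moderation, array weights, the replicate number as a block, an estimated correlation for lists and leaving out each sample in turn. A fit without CDAHFD sham samples 2 and 5 was added after the data were seen. For the opposition of diet and RIC effects, the 5 shared CDAHFD sham samples were split in 20 ways and 200 sets of unchanged groups were simulated, and splits of the 9 CDAHFD samples were refitted under the 3 rescalings. Up to 100 splits of the samples, the real one included, were fitted for each count.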

Results

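Liver RNA was sequenced in 19 mouse samples. The mice received normal chow (NC) or a choline-deficient high-fat diet with defined amino acids (CDAHFD), a diet used to produce steatohepatitis, and either remote limb ischemic conditioning (RIC), in which the blood flow of a limb is interrupted and restored, or a sham procedure. There were 5 NC sham, 5 NC RIC, 5 CDAHFD sham and 4 CDAHFD RIC samples. The labels call them replicates without saying that each came from a separate animal, so p-values measure the spread between these samples. Expression was deposited as FPKM, and 10577 genes with a mean of at least 1 FPKM were tested. The estimated depth was 15.9 to 26.4 M reads per sample, with group means of 18.6 ± 2.09 M in NC sham, 19.2 ± 1.98 in NC RIC, 19.2 ± 2.1 in CDAHFD sham and 22.2 ± 3.08 in CDAHFD RIC. At the mean depth 1 read in a gene of 2 kb was worth 0.0254 FPKM. Levels are given as mean FPKM ± SD (n = 5, or n = 4 for CDAHFD RIC), differences are on the log2(FPKM + 1) scale, and folds are ratios of mean FPKM.

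Samples separated first by diet and then by RIC. The first principal component held 75.6% of the variance and placed the NC samples between -51.9 and -39.7 and the CDAHFD samples between 36.3 and 64.4. On the second component (5.61%), CDAHFD RIC lay at 15.9 to 24.5 and CDAHFD sham at -25.7 to -0.0335, while NC RIC lay at 0.718 to 6.13 and NC sham at -10.8 to -0.659. Samples 2 and 5 of the CDAHFD sham group stood apart on the fourth component, at 20.6 and 16.6 against -9.3 to -3.8 in the other three. Median correlations of log2 values were 0.976 to 0.984 within groups and 0.867 between NC sham and CDAHFD sham. The sum of FPKM differed between groups, with 490879 ± 7664 in NC sham, 502693 ± 8370 in NC RIC, 471476 ± 23388 in CDAHFD sham and 436127 ± 11501 in CDAHFD RIC. In every sample Xist was at most 0.0235 FPKM and the Y-linked Ddx3y at least 12 FPKM.

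**Figure D1:**
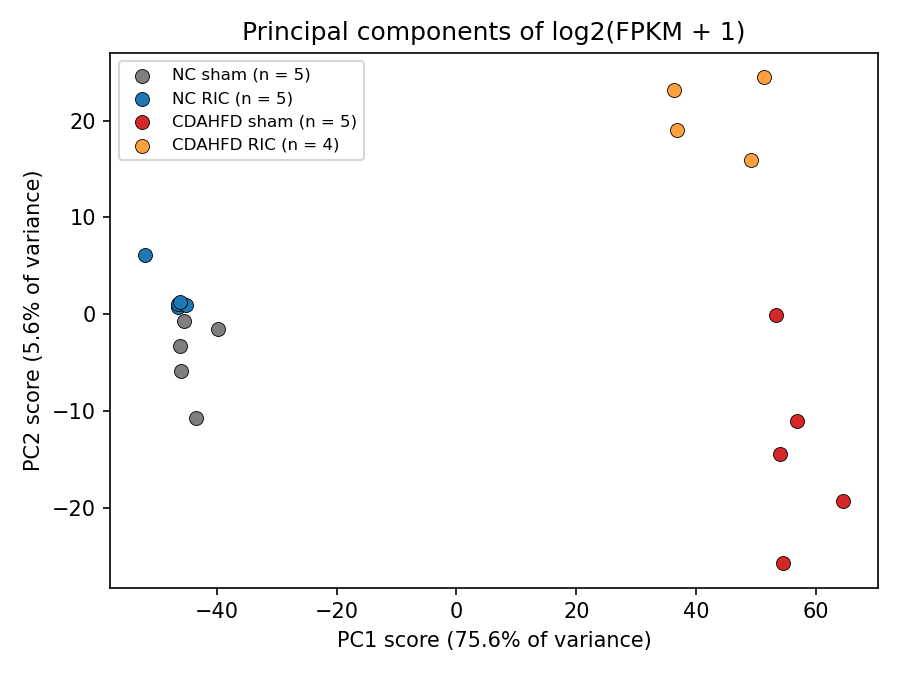
Positions of the 19 samples on the first (75.6% of variance, horizontal) and second (5.61%, vertical) principal components of log2(FPKM + 1), 1 point per sample, coloured by group. The NC samples sit between -51.9 and -39.7 on the horizontal axis and the CDAHFD samples between 36.3 and 64.4.

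The first comparison asked what CDAHFD does to the liver, between CDAHFD sham and NC sham. Genes of macrophages, matrix, cytokines and proliferation were higher on CDAHFD, and genes of hepatocyte function and of sterol synthesis were lower. With an estimated correlation 7 lists of hepatocyte function and metabolism still passed, and none of the higher lists nor sterol synthesis did. Lcn2, which encodes a secreted siderophore-binding protein, rose from 1.09 ± 0.304 to 158 ± 43.6 FPKM (145-fold, log2 difference 6.22, adjusted p = 1.23e-13; chromosome 2, 32384633 to 32388252, coordinates here and below from the GENCODE annotation of the mm10 assembly). Galectin-3 (Lgals3) rose from 1.23 ± 0.309 to 116 ± 24.2 (94.1-fold, adjusted p = 1.66e-15), S100a11 53.1-fold to 164 ± 38.4 (log2 difference 5.40) and the tetraspanin Cd63 83.2-fold to 56.5 ± 9.85 (5.09). Gpnmb, a glycoprotein of lipid-laden macrophages, was listed at 0 in all but 1 of the NC sham samples and at 42.6 ± 7.77 on CDAHFD (log2 difference 5.43). The drug-metabolising Cyp2a4 (6.25), Cyp2b9 (5.81) and Gsta1 (5.39) rose to 103 ± 17.9, 56.9 ± 12.5 and 93.4 ± 28 FPKM. The 8 largest falls were all in major urinary proteins, secreted pheromone carriers. Mup7 fell from 4717 ± 676 to 0.441 ± 0.56 FPKM (log2 difference -11.74, adjusted p = 1.77e-17; chromosome 4, 60066469 to 60070475), followed by Mup15 (-10.81), Mup17 (-9.51), Mup18 (-9.20), Mup10 (-9.10), Mup11 (-9.02), Mup16 (-8.48) and Mup19 (-8.47). Mup3 kept 128 ± 32.5 of 9475 ± 548 FPKM (-6.22). Reads of these near-identical genes, and of Cyp2a, Cyp2b and Gsta members, can be assigned to the wrong copy, so single members are uncertain. The Mup share of all FPKM was 5.65% in NC sham and 0.392% in CDAHFD sham.

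Macrophage, matrix and inflammation lists rose together. Counts cover only members that passed the expression filter, which a gene near 0 on NC passes only through its CDAHFD level. Tested were 19 of 26 cytokine, 28 of 36 matrix, 11 of 22 cell cycle and 6 of 14 cholangiocyte genes. Of all 10577 tested genes 6762 were called higher. All 20 tested monocyte and lipid-associated macrophage markers rose (median log2 difference 3.23, adjusted p = 8.96e-09, and adjusted p = 0.179 with an estimated correlation). Trem2, a lipid receptor of macrophages, rose from 0.0631 ± 0.0432 to 6.38 ± 0.806 FPKM (log2 difference 2.79, adjusted p = 5.69e-12), Spp1 (osteopontin) from 21.9 ± 7.08 to 267 ± 130.1 (3.47), the protease Ctss from 12.6 ± 1.01 to 266 ± 32.5 (4.29) and the macrophage receptor Adgre1 from 1.61 ± 0.304 to 7.45 ± 1.92 (1.67). All 28 extracellular matrix and fibrosis genes rose (median 2.03, adjusted p = 3.52e-07, and adjusted p = 0.269 with an estimated correlation), as did 14 of 14 stellate cell markers (median 1.34, adjusted p = 0.00512, and adjusted p = 0.332 with an estimated correlation). Acta2, the smooth muscle actin of activated stellate cells, rose from 0.215 ± 0.207 to 8.44 ± 4.09 FPKM (39.3-fold, log2 difference 2.87, adjusted p = 1.23e-09; chromosome 19, 34241090 to 34255590), the collagen chain Col1a1 from 0.0782 ± 0.0502 to 8.67 ± 4.77 (3.02; chromosome 11, 94936224 to 94953042) and Tgfb1 from 0.243 ± 0.0957 to 2.56 ± 0.392 (1.51). The protease inhibitor Timp1 was listed at 0 in the NC sham samples and at 7.51 ± 2.67 FPKM on CDAHFD (3.03). All 19 cytokines and chemokines rose (median 2.01, adjusted p = 1.01e-05, and adjusted p = 0.179 with an estimated correlation), among them the monocyte attractant Ccl2 (0.048 to 12 FPKM, 3.62), Cxcl10 (2.82) and Il1b (1.42). All 21 interferon response genes rose (median 1.38, adjusted p = 8.93e-04, and adjusted p = 0.282 with an estimated correlation), with Isg15 at 2.37 and Ifi27l2a at 3.0.

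Cell cycle, immediate early and oxidative stress genes also rose, though none of these lists passed with an estimated correlation, and ER stress genes were mixed (5 of 20 rose, 7 fell and 8 did not pass; below other genes by camera, adjusted p = 9.03e-04, and adjusted p = 0.269 with an estimated correlation). Of 11 cell cycle genes 10 rose, 0 fell and 1 did not pass (median 1.96, adjusted p = 0.00242, and adjusted p = 0.209 with an estimated correlation). Cyclin D1 (Ccnd1) went from 1.18 ± 0.136 to 58.3 ± 13.8 FPKM (49.3-fold) and Mki67 from 0.0977 ± 0.0329 to 4.93 ± 1.6 (2.39). Of 15 immediate early and NR4A genes, which respond within minutes to many stimuli, 14 rose, 0 fell and 1 did not pass (median 1.49, adjusted p = 0.00512, and adjusted p = 0.276 with an estimated correlation), with Jun at 3.43 ± 1.22 to 35.1 ± 4.5 FPKM (10.2-fold) and the nuclear receptor Nr4a1 at 0.155 to 2.26 (1.49). The stress transcription factor Atf3 rose from 0.30 ± 0.202 to 23.6 ± 2.87 FPKM (78.4-fold, log2 difference 4.25). Of 20 NRF2 and oxidative stress genes 15 rose, 1 fell and 4 did not pass (median 1.15, adjusted p = 0.0148, and adjusted p = 0.209 with an estimated correlation), including heme oxygenase Hmox1 (3.62) and Nqo1 (2.30). Lists that did not pass included Kupffer cell markers (10 of 13 rose, 2 fell, adjusted p = 0.422), sinusoidal endothelial markers (14 of 15 rose, adjusted p = 0.226), cholangiocyte markers (6 of 6 rose, adjusted p = 0.118) and acute phase genes (15 of 21 rose, 5 fell, adjusted p = 0.977). The camera test sets the moderated test statistics of a list, not its log2 differences, against those of all other genes. The median difference of all genes was 0.45. For acute phase genes the test pointed down although their median of 1.10 lay above that. Under quantile normalization, where the median of all genes was -0.04, the test pointed up. The cause was not tested.

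Genes of hepatocyte function fell. Of 20 growth hormone responsive and sex-biased genes 2 rose, 16 fell and 2 did not pass (median -3.17, adjusted p = 7.65e-23, and adjusted p = 7.3e-04 with an estimated correlation). The transporter Slco1a1 fell from 93 ± 12.3 to 0.236 ± 0.0649 FPKM (394-fold). Of 24 cholesterol synthesis genes 0 rose, 17 fell and 7 did not pass (median -0.97, adjusted p = 2.02e-17, and adjusted p = 0.0644 with an estimated correlation), with Msmo1 at 23.4 to 2.03 FPKM, Cyp51 at 28.2 to 3.31, Tm7sf2 at 12.2 to 1.29 and the sterol sensor partner Insig1 at 52.4 to 8.33. Of 18 bile acid genes 0 rose, 11 fell and 7 did not pass (median -0.61, adjusted p = 3.66e-12, and adjusted p = 8.56e-04 with an estimated correlation). The alternative-pathway hydroxylase Cyp7b1 fell 18.5-fold and Slc27a5 2.78-fold, while Cyp7a1, the rate-limiting enzyme, stood at 41.4 ± 21.9 against 33 ± 13.9 FPKM (adjusted p = 0.434). Of 19 cytochrome P450 genes 3 rose, 11 fell and 5 did not pass (adjusted over the list alone, 3 rose and 12 fell; median -0.53, adjusted p = 3.07e-09, and adjusted p = 0.00634 with an estimated correlation), with Cyp2c54 at 269 to 5.81 FPKM. In choline and methionine metabolism, which supplies methyl groups, 4 rose, 9 fell and 7 did not pass of 20 (median -0.34, adjusted p = 9.64e-06, and adjusted p = 0.035 with an estimated correlation). Gnmt fell 3.34-fold from 629 ± 74.3 to 188 ± 50.1, Bhmt 3.29-fold and Ahcy 2.55-fold. Hepatocyte markers (10 of 18 fell, 2 rose; adjusted p = 4.06e-07, and adjusted p = 0.0342 with an estimated correlation), periportal genes (10 of 16 fell, 3 rose; adjusted p = 9.64e-06, and adjusted p = 0.0437 with an estimated correlation) and glucose metabolism genes (7 of 17 fell, 5 rose; adjusted p = 0.00129, and adjusted p = 0.0383 with an estimated correlation) also passed as lower. Glucose-6-phosphatase (G6pc), the last step of hepatic glucose release, fell from 159 ± 36.2 to 27.8 ± 16.9 FPKM (5.73-fold; chromosome 11, 101367561 to 101377903). Albumin (Alb) fell by 0.49 on the log2 scale (adjusted p = 0.00126), a call that ended with no filter and under quantile normalization (adjusted p over the alternatives 4.82e-06 to 1.0). Under quantile normalization its difference was 0, as for a gene of equal rank in every sample, so that setting could not test it.

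Lipid genes moved in both directions. Of 17 fatty acid synthesis genes 7 rose, 7 fell and 3 did not pass; the list's median was 0.18, its mean -0.07, and camera placed it below other genes (adjusted p = 0.00512, and adjusted p = 0.179 with an estimated correlation). Srebf1, a regulator of lipid synthesis, rose (log2 difference 0.83, adjusted p = 2.17e-04), Scd1 rose (0.99, 0.00624) and Fasn fell (-0.45, 0.0136). Of 26 fatty acid oxidation genes 6 rose, 4 fell and 16 did not pass (adjusted over the list alone, 4 rose and 3 fell; median 0.03, lower than other genes by camera, adjusted p = 0.00199, and adjusted p = 0.463 with an estimated correlation). Of 15 lipid droplet genes 10 rose and 3 fell (adjusted p = 0.581), with the fatty acid transporter Cd36 at 14 ± 4.24 to 105 ± 29.3 FPKM (2.83) and the droplet coat protein Plin2 at 0.68 (adjusted p = 0.0197). The lipoprotein list (7 of 16 rose, 5 fell, median 0.18) also passed below other genes (adjusted p = 0.0403, and adjusted p = 0.179 with an estimated correlation) and turned upward under quantile normalization, where it did not pass. Cpt1a, an enzyme of fatty acid entry into mitochondria, rose from 60.4 ± 5.76 to 74.4 ± 5.48 FPKM (log2 difference 0.30, adjusted p = 0.00955), but its difference was -0.28 under median-ratio scaling (adjusted p over the alternatives 0.00398 to 0.456). The hormone gene Fgf21 stood at 15 ± 8.09 against 8.18 ± 2.26 (adjusted p = 0.0439) and lost its call on leaving out any of 6 samples (adjusted p up to 0.151 without one). Plin2 lost it without NC sham 3 or 4 or CDAHFD sham 2 (up to 0.0653). The Fgf21 call also ended in 6 of 11 alternatives, among them median-ratio scaling and quantile normalization (up to 0.641). Median-ratio scaling and a fit without CDAHFD sham 2 and 5 ended the calls of Plin2 (up to 0.751) and Scd1 (up to 0.261), array weights that of Plin2, and quantile normalization that of Srebf1 (0.165).

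In all, limma called 7852 genes at an adjusted p under 0.05, 6762 higher and 1090 lower. A doubling or more was called for 1809 genes and a halving or more for 323. The samples of both groups did not overlap for 6269 of the 10577 tested genes, where chance gives 0.794%, and 6243 of these were called. The median of all tested genes was 0.45, which became 0.57 with values rescaled to a common sum, 0.00 with median-ratio scaling and -0.04 with quantile normalization. The share of calls that were higher was 86.1% as deposited, 50% with median-ratio scaling and 47.6% with quantile normalization, so the balance of rises and falls depended on the scaling. Of 33 lists 24 passed, 9 higher and 15 lower, and 7 of them held with an estimated correlation.

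**Figure D2:**
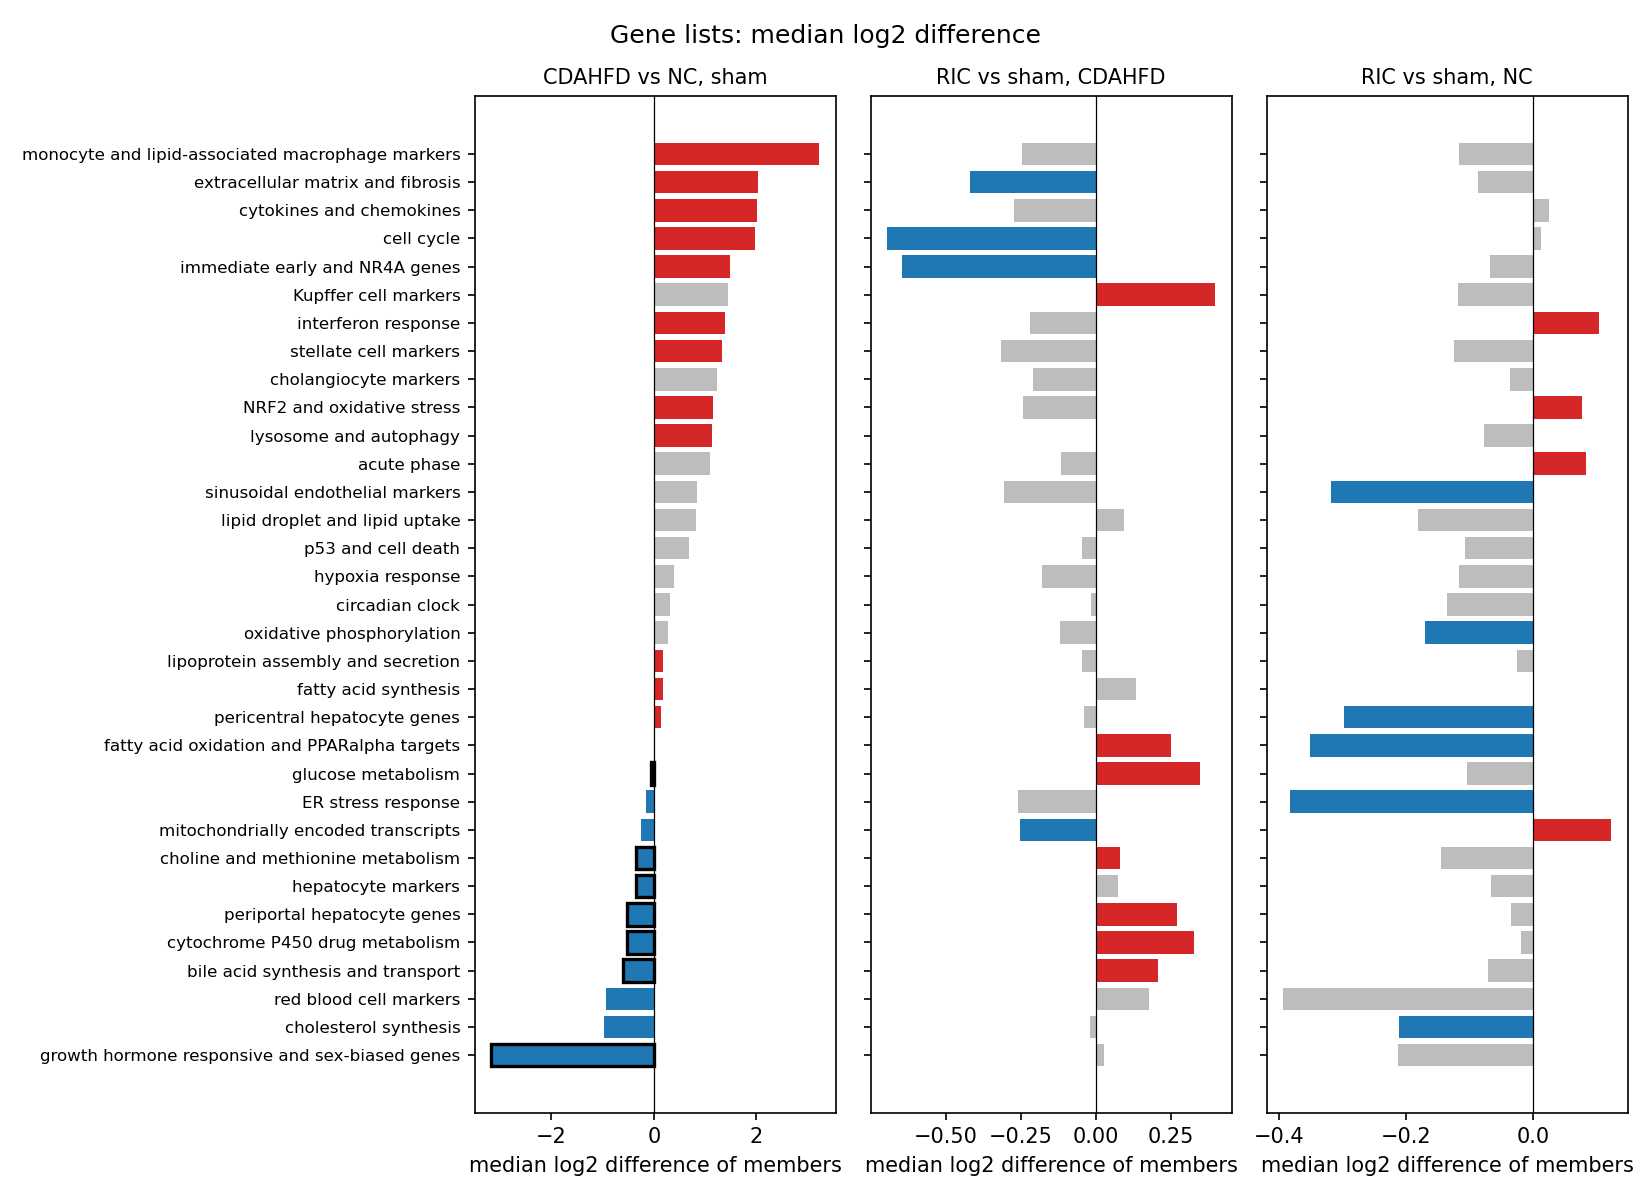
Median log2 difference of the members of each gene list (horizontal bars) for CDAHFD against NC in sham mice, RIC against sham on CDAHFD and RIC against sham on NC. Coloured bars passed the camera test against other genes (red, median above 0; blue, median below 0), grey bars did not, and a black outline marks the 7 lists, all in the diet panel, that also passed with an estimated correlation. The test's direction is relative to all genes and can differ from the sign of the median.

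The main question of the series was what RIC does in the CDAHFD liver, compared between CDAHFD RIC and CDAHFD sham. Lists of glucose, fatty acid oxidation, bile acid, cytochrome P450 and periportal genes were higher after RIC, and matrix, immediate early and cell cycle genes and several chaperone genes were lower. None of these lists passed with an estimated correlation, and 56 of 100 splits of the samples, the real one included, gave as many passing lists. Igfbp1, a hepatic binding protein induced in fasting, rose from 37 ± 24.9 to 196 ± 90.3 FPKM (5.29-fold, log2 difference 2.59, adjusted p = 0.00167; chromosome 11, 7197782 to 7202546), G6pc from 27.8 ± 16.9 to 107 ± 42.5 (3.86-fold, log2 difference 2.13, adjusted p = 0.00273) and Pdk4, which blocks pyruvate oxidation, from 12.1 ± 4.79 to 54.6 ± 23.5 (4.5-fold, 2.06). Without CDAHFD sham 2 and 5, a fit chosen after the data were seen, the differences were 1.76 for Igfbp1, 1.35 for G6pc and 1.68 for Pdk4. The ubiquitin ligase Rnf125 rose 6.92-fold to 23.5 ± 5.49 (2.67), Upp2 4.02-fold, Gpcpd1 4.28-fold and the G-protein regulator Rgs16 3.02-fold (adjusted p = 0.0243). AC147560.1, a gene named by its clone and not placed by the annotation, rose from 0.0925 ± 0.0847 to 39.9 ± 4.68 (5.22). Its FPKM also split within the NC groups, at 22.8 to 25.2 in NC sham 1, 4 and 5 against 0.139 and 0.194 in NC sham 2 and 3, and at 0.185 in NC RIC 5 against 19.2 to 24.6 in the other NC RIC samples. Its difference is therefore uncertain as an effect of RIC. The stress-induced chaperone Hspa1b fell from 37 ± 13.1 to 1.79 ± 0.548 FPKM (20.6-fold, log2 difference -3.71, adjusted p = 6.86e-08; chromosome 17, 34956436 to 34959238), its near-identical copy Hspa1a from 9.21 ± 3.66 to 0.551 ± 0.158 (16.7-fold), Hsph1 from 16.4 ± 2.65 to 2.7 ± 0.698 (6.06-fold) and Dnajb1 from 18.1 ± 1.82 to 5.09 ± 0.523 (3.55-fold, adjusted p = 3.6e-08). Reads of Hspa1a and Hspa1b cannot be told apart over most of their length. Hspa8 fell from 410.1 ± 62.5 to 214 ± 31.5 (-0.93; chromosome 9, 40800984 to 40810087). The small nucleolar RNAs Snord14e (-4.11, 28 to 0.0174 FPKM) and Snord14c (-2.10) lie inside Hspa8. Snord14e also split within groups, at 5.41 to 9.85 FPKM in NC sham 1 to 3 against 0.00968 and 0.0243 in NC sham 4 and 5, at 1.48 and 14.1 in NC RIC 1 and 4 against at most 0.0652 in the others, and at 0.0506 in CDAHFD sham 3 against 29.5 to 43.3 in the others. Its difference is uncertain as an effect of RIC. Angptl8, a lipid hormone gene induced by feeding, fell from 71.4 ± 32.5 to 9.46 ± 2.97 (7.55-fold, log2 difference -2.72, adjusted p = 3.19e-05). The mitochondrial tRNA mt-Ti fell from 101 to 22.5 FPKM (-2.20).

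Matrix, immediate early and cell cycle genes fell as lists. Of 28 extracellular matrix and fibrosis genes 0 rose, 13 fell and 15 did not pass (adjusted over the list alone, 15 fell; median -0.42, adjusted p = 0.0032, and adjusted p = 0.79 with an estimated correlation). Thbs1 fell 4.24-fold (-1.46), Ctgf 3.01-fold (-1.61), Timp1 from 7.51 ± 2.67 to 3.29 ± 1.72 FPKM (log2 difference -1.03, adjusted p = 0.00515) and Col1a1 from 8.67 ± 4.77 to 3.94 ± 3.11 (-1.02, adjusted p = 0.0295). Col1a1 kept its call only on leaving out CDAHFD sham 2 or 5 or CDAHFD RIC 4, and its adjusted p without 1 sample ran from 0.00341 to 0.125. Acta2 fell from 8.44 ± 4.09 to 1.67 ± 0.736 (5.05-fold, log2 difference -1.75, adjusted p = 7.66e-05), but the stellate cell list did not pass (4 of 14 fell, 1 rose, adjusted p = 0.302), and Tgfb1 stood at -0.17 (adjusted p = 0.216). Of 15 immediate early genes 0 rose, 10 fell and 5 did not pass (median -0.64, adjusted p = 0.00104, and adjusted p = 0.439 with an estimated correlation), with Jun at 35.1 ± 4.5 to 13.8 ± 5.69 FPKM (2.54-fold), Ier3 at -1.28 and Nr4a1 at -0.70 (adjusted p = 0.0351, lost on leaving out any of 6 of 9 samples, up to 0.101, and in 7 of 10 alternatives, each rescaling included, up to 0.145). Of 11 cell cycle genes 0 rose, 7 fell and 4 did not pass (median -0.69, adjusted p = 0.021, and adjusted p = 0.643 with an estimated correlation), among them Mki67 (4.93 to 2.13 FPKM) and Ccnb2 (8.7 to 4.36). The list call ended without CDAHFD RIC 4, and without CDAHFD sham 2 and 5 together, where the median minus that of all genes was -0.11 (adjusted p = 0.138). These samples scored 1.52 and 1.51 on the list, against 0.719 to 1.08 in the other CDAHFD sham samples and 0.62 to 0.711 in CDAHFD RIC. Without CDAHFD RIC 3 the matrix list no longer passed.

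Several metabolic lists passed as higher than other genes, though most of their members did not pass singly. Of 17 glucose metabolism genes 7 rose, 1 fell and 9 did not pass (adjusted over the list alone, 9 and 1; median 0.35, adjusted p = 0.00104, and adjusted p = 0.121 with an estimated correlation). Glycogen synthase Gys2 went from 89.9 to 206 FPKM (1.18), the coactivator Ppargc1a from 2.69 to 7.09 (1.09) and the glucose-sensitive Txnip from 30.3 to 88.7 (1.53). Of 26 fatty acid oxidation genes 5 rose, 0 fell and 21 did not pass (median 0.25, adjusted p = 0.00262, and adjusted p = 0.79 with an estimated correlation). The list's score was -0.149 in CDAHFD RIC 1, below the CDAHFD sham samples (-0.142 to 0.291), and 0.498 to 0.591 in the other CDAHFD RIC samples. The receptor Ppara rose from 7.35 to 20.7 (2.82-fold) and Cpt1a from 74.4 ± 5.48 to 101 ± 12.3 (log2 difference 0.43, adjusted p = 0.00557). Of 16 periportal genes 4 rose, 0 fell and 12 did not pass (adjusted p = 3.41e-04, and adjusted p = 0.135 with an estimated correlation), including the histidine-degrading Hal (1.04) and the urea cycle enzyme Cps1 (0.78). Of 19 cytochrome P450 genes 7 rose, 0 fell and 12 did not pass (adjusted over the list alone, 9 rose and 1 fell; adjusted p = 3.41e-04, and adjusted p = 0.122 with an estimated correlation), among them Cyp3a13 (0.98) and Cyp3a25 (0.78). Of 18 bile acid genes 6 rose, 0 fell and 12 did not pass (adjusted p = 0.00104, and adjusted p = 0.122 with an estimated correlation), with Slc27a5 at 0.53 and Slco1a1 at 0.68, while Cyp7a1 stood at -0.40 (adjusted p = 0.417). In choline and methionine metabolism 3 rose, 1 fell and 16 did not pass of 20 (adjusted p = 0.0219, and adjusted p = 0.439 with an estimated correlation). Gnmt rose 1.93-fold, Mat1a (0.69) and Ahcy (0.56) rose, Pemt fell (-0.32), and Bhmt stood at 0.54 (adjusted p = 0.182). Leaving out CDAHFD RIC 3 ended the calls of this list, of Mat1a (adjusted p = 0.0536) and of Pemt (0.070). The Pemt call also ended with a common sum and with median-ratio scaling (adjusted p up to 0.146), and the Ahcy call with only the groups compared fitted (0.0547). Hepatocyte markers (4 of 18 rose, 1 fell, median 0.08, adjusted p = 0.149) and pericentral genes (1 of 16 rose, 3 fell, adjusted p = 0.552) did not pass.

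Among immune and lipid genes some rose and others fell. Of 13 Kupffer cell markers, which mark resident macrophages, 5 rose, 2 fell and 6 did not pass (adjusted over the list alone, 7 rose and 2 fell; adjusted p = 0.0404, and adjusted p = 0.79 with an estimated correlation), and the list call was lost under each rescaling tried and without CDAHFD sham 1 or 4 or CDAHFD RIC 2 or 3. Adgre1 rose to 12.9 ± 5.67 FPKM (log2 difference 0.67, adjusted p = 0.0237), Cd163 (0.78, 0.0242) and Timd4 (0.56) rose, and Id3 fell (-0.99). The Adgre1 call was lost without CDAHFD sham 1 or CDAHFD RIC 2 (adjusted p up to 0.0943) and the Cd163 call without CDAHFD sham 1 or CDAHFD RIC 2, 3 or 4 (up to 0.091). Ccl2 fell from 12 ± 1.83 to 7.16 ± 1.75 FPKM (log2 difference -0.69, adjusted p = 0.00142; adjusted p = 0.119 with a pseudocount of 0.1, range over the alternatives from 7.1e-04), and the cytokine list did not pass (6 of 19 fell, 2 rose, adjusted p = 0.103). Interferon genes (6 of 21 fell, adjusted p = 0.326) and lipid-associated macrophage markers (2 of 20 fell, adjusted p = 0.326) did not pass either. Differences that did not pass were -0.30 for Trem2 (adjusted p = 0.156; 0.0456 without CDAHFD RIC 4), -0.47 for Spp1 (0.33) and -0.22 for Il1b (0.491). In fatty acid synthesis 3 of 17 rose and 1 fell (adjusted p = 0.103), with Srebf1 at log2 difference 0.67, adjusted p = 0.011, Scd1 at 0.30 (0.505) and Fasn at -0.09 (0.705). In the lipid droplet list 3 of 15 rose (adjusted p = 0.0955), with Cd36 at 0.68 (0.0484, lost without any of 7 of 9 samples, up to 0.141, and in 5 of 11 alternatives, up to 0.106) and Plin2 at 0.29 (0.442). Alb stood at 0.31 (adjusted p = 0.0756; 0.0228 at the lowest without CDAHFD sham 2 or CDAHFD RIC 2, where it passed) and Fgf21 at 0.24 (0.61). Of 15 mitochondrially encoded transcripts 0 rose, 7 fell and 8 did not pass (adjusted over the list alone, 11 fell; median -0.25, adjusted p = 0.0193, and adjusted p = 0.79 with an estimated correlation), with mt-Rnr1 at 532 to 225 FPKM (-1.27).

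**Figure D3:**
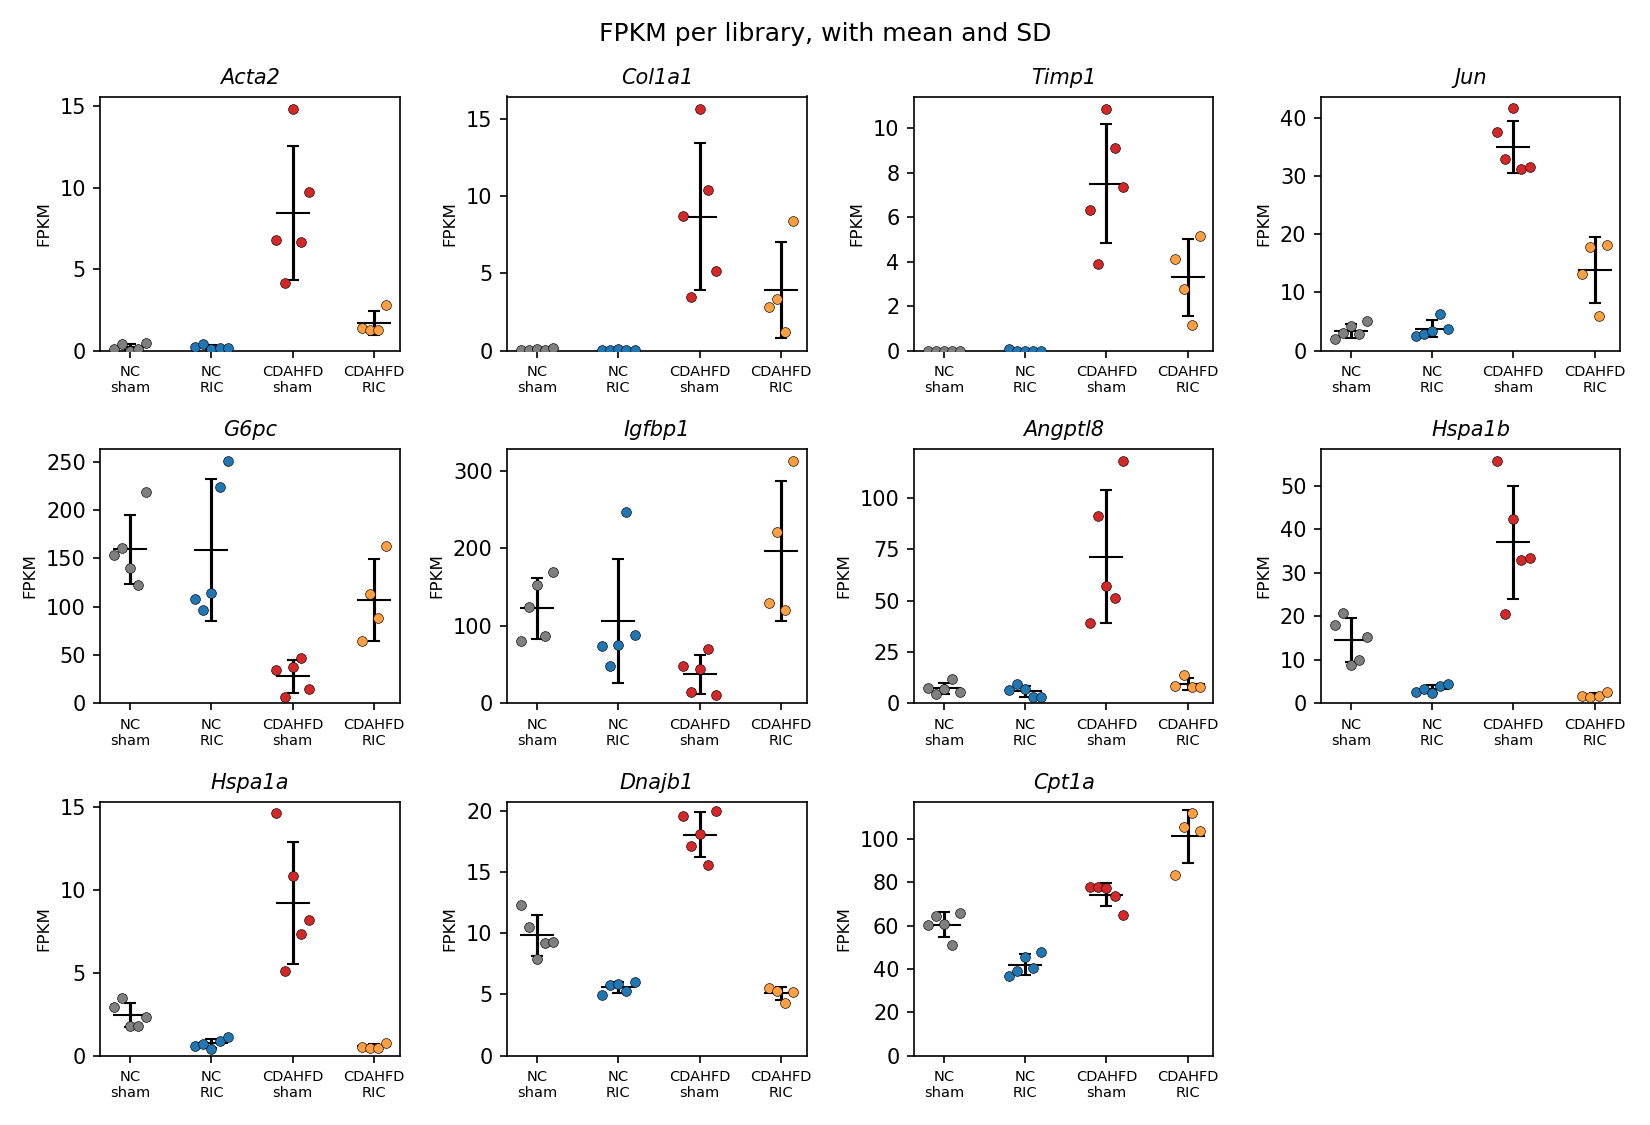
FPKM of 11 genes in each sample (points) by group, with the group mean (horizontal mark) and SD (bars). Acta2, Col1a1, Timp1, Jun, Angptl8 and the heat shock genes were lower in CDAHFD RIC than in CDAHFD sham, and G6pc, Igfbp1 and Cpt1a were higher.

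For RIC on CDAHFD limma called 2886 genes, 922 higher and 1964 lower, with 65 at least doubled and 94 at least halved. The groups did not overlap for 1944 of the 10577 tested genes, where chance gives 1.59%, and 1695 of these were called. The median of all genes was -0.08, and 0.01 with a common sum. Higher genes made up 31.9% of calls as deposited, 56.9% with a common sum, 55.8% with median-ratio scaling and 50.5% with quantile normalization. Of 33 lists 11 passed, 7 higher and 4 lower, and none held with an estimated correlation. As many lists passed in 56 of 100 splits of the 9 samples, the real one included, so chance was not excluded for that count. List calls also ended for cell cycle (pseudocount of 0.1, only the groups compared fitted), matrix (a mean of at least 5 FPKM), mitochondrially encoded transcripts (median-ratio scaling, quantile normalization, only the groups compared fitted) and choline and methionine metabolism (without CDAHFD sham 2 and 5). Without these 2 samples the cytokine list passed as lower. Rgs16 lost its call without CDAHFD sham 2 or 5 or CDAHFD RIC 1 (adjusted p up to 0.0748), with no filter, with array weights and without CDAHFD sham 2 and 5 together (up to 0.175). Fitting only the groups compared also ended the calls of Timp1 (0.0526), Srebf1 (0.0526), Col1a1, Ccnb2, Adgre1 and Cd163. No filter ended those of Col1a1 (up to 0.134), Adgre1 (up to 0.0782) and Cd163 (up to 0.0683). A pseudocount of 0.1 and the fit without both samples ended that of Ccnb2 (up to 0.105). Alb passed with a common sum and without both samples. With only its own groups fitted, 1868 genes passed with a mean of at least 1 FPKM, and 1480 of the genes with a mean of at least 5 FPKM passed.

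RIC effects ran opposite to diet effects for most genes that the diet changed. Of the 7852 genes called for CDAHFD in sham mice, 74.9% had a RIC difference of the opposite sign. This held for 74.7% of the genes raised by the diet and 76.2% of those lowered, while 60.5% of all tested genes were lower after RIC. Both comparisons share the CDAHFD sham samples, which alone can give opposite signs. Simulated unchanged groups gave 66.8% (50% to 81.8% between the outer quantiles of 200 simulations). That share was taken over all tested genes without any diet effect, so it is not a chance level for genes the diet changed. With the 5 shared samples split between the comparisons, the share was 72.7% (65% to 80% over 20 splits). The covariance of both effects across genes was -0.133, -0.113 with the samples split and -0.0118 in the simulation, a difference of -0.121. The correlation across genes, which are not independent, was -0.414, against -0.468 in the simulation, which held no diet effect, and -0.337 with the samples split. Among genes called in both, 1759 were raised by diet and lowered by RIC, 376 lowered by diet and raised by RIC, 184 raised in both and 32 lowered in both. The shared samples favour opposite calls here as well, and no count for unchanged groups was made. The share was 63.8% with values rescaled to a common sum. As many opposite signs were found in 10 of 100 splits of the 9 CDAHFD samples, so chance was not excluded for the share, and as low a covariance in only 1, the real one. The size of the covariance also grows with that of the RIC differences, and the real split called the most genes. For the correlation the other splits reached -0.441, so chance was not excluded for it either.

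**Figure D4:**
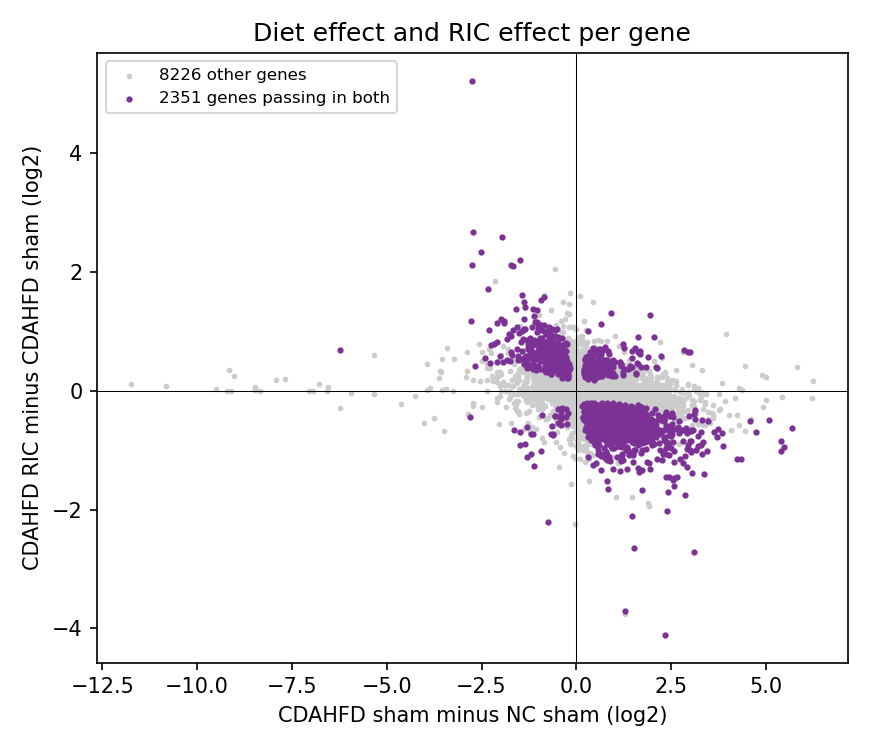
Log2 difference of CDAHFD sham minus NC sham (horizontal) against that of CDAHFD RIC minus CDAHFD sham (vertical) for 10577 tested genes, 1 point per gene, with the 2351 genes that passed in both comparisons in purple. Of those, 1759 lie at lower right and 376 at upper left. Both axes share the CDAHFD sham samples.

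RIC in the chow-fed liver was compared between NC RIC and NC sham, and few genes were called. The linker histone gene Hist1h1c rose from 20.7 ± 5.22 to 57.2 ± 21.4 FPKM (2.77-fold, log2 difference 1.38, adjusted p = 0.00527). Among glutathione transferases, which were not tested as a list, Gsta1 rose from 1.2 ± 0.417 to 3.66 ± 1.13 (3.04-fold), Gsta2 from 16.3 ± 5.03 to 32.6 ± 4.45 (1.0) and Mgst3 from 4.8 ± 0.411 to 7.79 ± 0.902 (log2 difference 0.60, adjusted p = 0.00566). Hepcidin (Hamp), the iron hormone, rose from 872 ± 180.0 to 1767 ± 396 (log2 difference 1.02, adjusted p = 0.0496). Rises were also called for the oxysterol hydroxylase Cyp39a1 (0.85, 0.0455), the immunoglobulin segment Igkv1-110 (0.92, 0.0496), the clone-named AC153546.1 (0.65, 0.0281), Alb (0.50, 0.0496) and mt-Nd1 (0.42, 0.040), with adjusted p second in each pair. Metal-binding Mt1 (log2 difference 2.42, adjusted p = 0.0138) and Mt2 (log2 difference 3.04, adjusted p = 0.0141) also passed, although NC sham 3 overlapped the RIC samples. Hspa1b fell from 14.5 ± 5.08 to 3.25 ± 0.937 FPKM (4.46-fold, log2 difference -1.83, adjusted p = 0.00462), Hspa8 from 414 ± 57.1 to 243 ± 50.7 (-0.78), Dnajb1 from 9.84 ± 1.66 to 5.57 ± 0.448 (log2 difference -0.71, adjusted p = 0.00495) and Hspa1a (-0.98, 0.0255). Fgf21 fell from 8.18 ± 2.26 to 2.8 ± 1.21 (2.93-fold, log2 difference -1.30, adjusted p = 0.046; chromosome 7, 45613886 to 45615490), the elongase Elovl3 from 176 ± 65.1 to 77 ± 29.3 (-1.20), Txnip from 59.3 ± 18 to 27.6 ± 13.4 (-1.16) and the stress transcription factor Atf5 (-0.84). Palld (-0.84), Tbc1d8 (-0.92) and Mrpl53 (-0.79) also fell. Cpt1a fell from 60.4 ± 5.76 to 42 ± 4.75 (log2 difference -0.52, adjusted p = 0.0182; chromosome 19, 3322334 to 3385733). Differences were -0.04 for Col1a1 (adjusted p = 0.967), -0.01 for Acta2 (0.993), 0.03 for Ccl2 (0.936) and 0.46 for Nr4a1 (0.305), and none of these passed.

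In the lists, fatty acid oxidation was lower after RIC on NC: 0 rose, 2 fell and 24 did not pass of 26 (adjusted over the list alone, 8 fell; median -0.35, adjusted p = 2.96e-05, and adjusted p = 0.736 with an estimated correlation). Oxidative phosphorylation also passed as lower with 0 of 24 genes passing (adjusted over the list alone, 5 fell; median -0.17, adjusted p = 4.58e-04, and adjusted p = 0.736 with an estimated correlation), as did ER stress (median -0.38, adjusted p = 0.0197, and adjusted p = 0.736 with an estimated correlation), sinusoidal endothelial (median -0.32, adjusted p = 0.0159, and adjusted p = 0.736 with an estimated correlation), pericentral (median -0.30, adjusted p = 0.0273, and adjusted p = 0.736 with an estimated correlation) and cholesterol synthesis genes (median -0.21, adjusted p = 0.0454, and adjusted p = 0.745 with an estimated correlation). Higher lists were interferon response (median 0.10, adjusted p = 4.58e-04, and adjusted p = 0.736 with an estimated correlation), acute phase (median 0.08, adjusted p = 0.00219, and adjusted p = 0.736 with an estimated correlation), mitochondrially encoded transcripts (median 0.12, adjusted p = 0.00219, and adjusted p = 0.736 with an estimated correlation) and NRF2 (median 0.08, adjusted p = 0.0472, and adjusted p = 0.736 with an estimated correlation; adjusted over the list alone, 3 rose and 2 fell). Of 33 lists 10 passed, 4 higher and 6 lower. As many passed in 26 of 100 splits of the 10 samples, so chance was not excluded for that count. Leaving out single samples ended list calls for cholesterol synthesis (4 of 10 samples), NRF2 (5), ER stress (3), pericentral (2) and sinusoidal endothelial genes (2).

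limma called 125 genes for RIC on NC, 34 higher and 91 lower, of 1747 at an unadjusted p under 0.05, with 7 at least doubled and 5 at least halved. The groups did not overlap for 502 of the 10577 tested genes, where chance gives 0.794%, and 98 of these were called. Most genes without overlap thus had no call, and a missing call does not show that a gene was unchanged. The median of all genes was -0.06, -0.10 with a common sum and 0.00 with median-ratio scaling. The higher share of calls was 27.2% as deposited, 16.1% with a common sum, 62.2% with median-ratio scaling and 64.4% with quantile normalization. The count depended on single samples. It was 31, 13, 53 and 24 without NC sham 1, 2, 3 and 5, 184 without NC sham 4 and 15, 49, 75 and 80 without NC RIC 2, 3, 4 and 5. Among the named genes, Hist1h1c, Mgst3, Hspa1b, Dnajb1, Palld and Tbc1d8 kept their calls without any 1 sample. Hamp and Igkv1-110 lost theirs without each of 10, Alb and Mrpl53 without 9, Cyp39a1, Fgf21, Txnip and mt-Nd1 without 8, Elovl3 without 7, Atf5 without 6 and Hspa1a without 5. Gsta2 and AC153546.1 lost theirs without 4, Cpt1a without NC sham 2 or 5 or NC RIC 2, Gsta1 and Hspa8 without NC sham 2 or NC RIC 2, and Mt1 and Mt2 without NC sham 2 (adjusted p = 0.0537 and 0.0569). On leaving out 1 sample the log2 difference ran from 2.22 to 2.90 for Mt1 and from 2.77 to 3.69 for Mt2. The highest adjusted p on leaving out 1 sample was 0.138 for Hamp, 0.145 for Alb, 0.128 for Fgf21, 0.0789 for Hspa1a, 0.0616 for Cpt1a, 0.0667 for Gsta1 and 0.0607 for Hspa8. Alternative settings ended the calls of 18 of the 28 genes named for RIC on NC, a number that includes Col1a1, Acta2, Ccl2 and Nr4a1, which had no call to end. Alb lost its call in 7 of 10 (adjusted p up to 1.0), Elovl3 in 6 (up to 0.168), Hamp in 5 (0.144), Atf5 in 5 (0.122), Fgf21 (0.124), Txnip (0.122), Mrpl53 (0.115) and Igkv1-110 (0.143) in 4 each and Cyp39a1 in 3 (0.121). Under quantile normalization the Alb difference was 0, as for a gene of equal rank in every sample, so that setting could not test it. AC153546.1 lost it in 2. Gsta1, Gsta2, Hspa1a and mt-Nd1 lost theirs with no filter, Hspa8 and Cpt1a under quantile normalization, and Mt1 and Mt2 with only the groups compared fitted.

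The diet effect among conditioned mice was compared between CDAHFD RIC and NC RIC. As in sham mice, counts of rises cover only members that passed the expression filter. Cytokine genes (18 of 19 rose, adjusted p = 1.26e-05, and adjusted p = 0.196 with an estimated correlation), interferon response genes (19 of 21 rose, adjusted p = 0.0123, and adjusted p = 0.47 with an estimated correlation) and matrix genes were higher on CDAHFD here too. Col1a1 stood at 3.94 ± 3.11 against 0.0453 ± 0.0226 FPKM (log2 difference 2.04, adjusted p = 2.53e-05), Acta2 at 1.67 ± 0.736 against 0.199 ± 0.119 (1.12, 3.24e-04), Timp1 at 1.98, Ccl2 at 2.90, Trem2 at 2.51 and Spp1 at 3.12. Cpt1a rose 2.41-fold (log2 difference 1.25, adjusted p = 5.01e-09), Fgf21 6.13-fold (2.24) and Cd36 12.7-fold (3.59). Alb was lower (-0.67), and Nr4a1 (0.33, adjusted p = 0.216) and Bhmt (-0.46, 0.166) did not pass. Nr4a1 passed without NC RIC 4 (adjusted p = 0.00115). All 28 matrix genes (adjusted p = 9.56e-07, and adjusted p = 0.331 with an estimated correlation) and all 20 lipid-associated macrophage markers (adjusted p = 1.18e-10, and adjusted p = 0.181 with an estimated correlation) rose, 12 of 15 lipid droplet genes rose and 1 fell (adjusted p = 0.0434, and adjusted p = 0.47 with an estimated correlation), and 13 of 15 mitochondrially encoded transcripts fell and 1 rose (adjusted p = 1.28e-13, and adjusted p = 0.0882 with an estimated correlation). Of 26 fatty acid oxidation genes 17 rose and 1 fell (adjusted p = 0.864), and 16 of 20 growth hormone responsive genes fell and 2 rose (adjusted p = 1.48e-28, and adjusted p = 2.06e-04 with an estimated correlation). limma called 7435 genes, 6728 higher and 707 lower (90.5% higher; 94.6% with a common sum, 50.7% with median-ratio scaling and 47.2% with quantile normalization). The median of all genes was 0.42, 0.67 with a common sum and -0.01 with median-ratio scaling. With a mean of at least 5 FPKM 3401 genes passed. Quantile normalization ended the Acta2 (0.0505) and Alb calls, though it could not test Alb, whose difference it set to 0, and Bhmt passed with median-ratio scaling (0.00958). Of the genes called in both diet comparisons, which share no samples, 5802 were higher in both (4301 if independent) and 534 lower in both (72.9). Both use the same estimate of spread per gene, so their calls are not fully independent. Of 33 lists 20 passed and 4 held with an estimated correlation, and 8 of 100 splits gave as many, so chance was not excluded for that count.

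The interaction asked whether RIC acted differently in the diets, as the RIC difference on CDAHFD minus that on NC. The 10 genes with the smallest p were the phosphatase Ppm1k (log2 difference 1.56, adjusted p = 2.54e-04), Dnmbp (1.33), the acetyl-CoA carboxylase Acacb (1.38), Mgst3 (-1.08), Jmy (0.86), Bag4 (1.18), the folate carrier Slc25a32 (1.04), the vitamin C transporter Slc23a2 (1.31), Crebrf (1.22) and Zfp871 (log2 difference 0.96, adjusted p = 4.63e-04). Cpt1a, which rose after RIC on CDAHFD and fell on NC, differed by 0.95 (adjusted p = 9.31e-04) and Txnip by 2.69 (8.92e-04). The RIC effect was higher on CDAHFD for G6pc (2.22, 0.0373), Igfbp1 (2.98, 0.0171), Pdk4 (3.45, 0.00406) and Fgf21 (1.54, 0.0431). It was lower for Acta2 (-1.75, 0.00399), Ccl2 (-0.72, 0.0238), Nr4a1 (-1.16, 0.0376), Mt1 (-2.30, 0.0306), Hspa1b (-1.88, 0.00449), Hspa1a (-1.68, 0.0023) and Dnajb1 (-0.94, 0.00122). In NC sham Acta2, Ccl2 and Nr4a1 lay well below the pseudocount of 1 FPKM and had little room to fall on this scale. For these genes a fall on CDAHFD alone gives such a difference, whether or not RIC acts differently in the diets. For Hspa8 the diets did not differ by the test (-0.15, 0.691). Of 26 fatty acid oxidation genes 6 were higher and 0 lower in the interaction (adjusted over the list alone, 8 and 0; median 0.63, adjusted p = 1.11e-07, and adjusted p = 0.364 with an estimated correlation), and of 17 glucose metabolism genes 8 and 1 (10 and 2 adjusted over the list alone; median 0.48, adjusted p = 4.12e-04, and adjusted p = 0.0726 with an estimated correlation). In all 711 genes passed, 380 higher and 331 lower (53.4% higher, and 82.8% with a common sum, where the median of all genes was 0.10 instead of -0.03). Without NC sham 2 the count was 438, without CDAHFD sham 3 it was 469, without CDAHFD sham 2 and 5 together, chosen after the data were seen, 1266, and 386 with a mean of at least 5 FPKM. Single samples ended the calls of Fgf21 (12 of 19 samples, adjusted p up to 0.0929), G6pc (10, up to 0.0712), Nr4a1 (8, up to 0.0761) and Mt1 (6, up to 0.0664), and each rescaling ended that of Ccl2 (adjusted p over the alternatives up to 0.308, 5 of 9 lost). Alternatives also ended the calls of Nr4a1 (6 of 9, up to 0.0977) and Fgf21 (3 of 10, up to 0.11), and no filter those of G6pc (0.101), Mt1 (0.0831) and Igfbp1 (0.0514). Of 33 lists 15 passed, 8 higher and 7 lower, none with an estimated correlation. In total 11 of 100 splits gave as many, so chance was not excluded for that count. Between the RIC effects in both diets, which share no samples, 25 genes were lower in both (16.9 if independent), 4 higher in both (2.96), 11 lower on NC and higher on CDAHFD (7.93) and 7 the reverse (6.31). Both use the same estimate of spread per gene, which can raise counts of genes called in both above the independent level. Over all tested genes both RIC effects had a correlation of 0.15 and the same sign in 60.3%.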

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

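All tests of both patterns weighed here were chosen after the results were seen, as were the heat shock, fasting and feeding lists they use. Of 628 groups of values examined, 41 held 1 sample far from the rest of its group, against 31.4 expected by chance (about 1 in 20). On the log2(FPKM + 1) scale, NC samples stood apart with Cyp2a4 at 1.92 in NC sham 2 (nearest 0.23), Cyp2a4 at 1.96 in NC RIC 3 (nearest 0.53), Cyp2b9 at 0.11 in NC sham 2 (nearest 0) and Gsta1 at 0.57 in NC sham 2 (nearest 1.18). Near the floor, Gpnmb stood at 0.0128 in NC sham 3 and 0.0294 in NC RIC 3, Timp1 at 0.0745 in NC RIC 1 and Mup19 at 0.0353 in CDAHFD RIC 1, with 0 in the rest of their groups. Other NC samples apart were Tgfb1 at 0.25 in NC RIC 3 (nearest 0.31), Hspa8 at 8.38 in NC RIC 3 (nearest 7.85), AC147560.1 at 0.24 in NC RIC 5 (nearest 4.34), Mt1 at 6.16 in NC sham 3 (nearest 4.11) and Mt2 at 7.43 in NC sham 3 (nearest 4.68). The interaction genes added Ppm1k at 3.92 in NC sham 1 (nearest 4.28), Dnmbp at 2.23 in NC sham 4 (nearest 2.48), Crebrf at 2.38 in NC RIC 5 (nearest 2.84) and Slc25a32 at 3.57 in CDAHFD RIC 1 (nearest 3.48). Among CDAHFD sham samples there were Mup3 at 7.55 in CDAHFD sham 1 (nearest 6.93), Cpt1a at 6.05 in CDAHFD sham 5 (nearest 6.23) and Snord14e at 0.0712 in CDAHFD sham 3 (nearest 4.93). CDAHFD RIC 1 held Mup3 at 7.91 (nearest 6.33), Cyp2c54 at 4.43 (nearest 3.10) and Srebf1 at 3.60 (nearest 2.67). The other samples of that group gave Acta2 at 1.91 in CDAHFD RIC 4 (nearest 1.25), Hspa1b at 1.85 in CDAHFD RIC 4 (nearest 1.37), Mup17 at 0.59 in CDAHFD RIC 2 (nearest 0.0603) and Angptl8 at 3.90 in CDAHFD RIC 2 (nearest 3.23).

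List scores stood apart in 10 cases. They were fatty acid oxidation at -0.149 in CDAHFD RIC 1 (nearest 0.498), choline and methionine metabolism at -0.0584 in NC sham 4 (nearest 0.183), acute phase at -0.605 in NC RIC 2 (nearest -0.384), interferon response at -0.286 in NC RIC 3 (nearest -0.572) and NRF2 at -0.461 in NC RIC 2 (nearest -0.585). Sinusoidal endothelial markers scored 0.185 in NC sham 5 (nearest -0.337), 0.249 in CDAHFD sham 1 (nearest 0.614) and -0.262 in CDAHFD RIC 1 (nearest 0.471). The last 2 cases were p53 and cell death at 0.63 in CDAHFD sham 3 (nearest 0.448) and oxidative phosphorylation at -0.307 in NC RIC 4 (nearest -0.213). Of the totals per sample, the FPKM sum was 418945 in CDAHFD RIC 2 (nearest 441088), entries without a name took 0.123% in NC RIC 4 (nearest 0.137%), CDAHFD sham 1 had 20998 genes above 0 (nearest 21842), and Mup genes took 0.527% of the FPKM in CDAHFD RIC 1 (nearest 0.241%).

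The RIC effect differed between diets by the limma interaction for 50 named genes, given here as the effect on CDAHFD minus that on NC with the adjusted p in parentheses. Part of them were named for large RIC differences or a small interaction p, so 50 is not a rate. Of all 10577 tested genes 711 passed. Among metabolic genes the values were Igfbp1 2.98 (0.0171), G6pc 2.22 (0.0373), Pdk4 3.45 (0.00406), Angptl8 -2.39 (0.0047), Txnip 2.69 (8.92e-04), Ppara 1.42 (0.00779), Cpt1a 0.95 (9.31e-04), Gys2 1.33 (0.00186), Ppargc1a 1.36 (0.0115), Fgf21 1.54 (0.0431) and Acacb 1.38 (2.54e-04). For heat shock and early response genes they were Hspa1b -1.88 (0.00449), Hspa1a -1.68 (0.0023), Hsph1 -1.78 (9.31e-04), Dnajb1 -0.94 (0.00122), Jun -1.48 (0.0218), Ier3 -1.47 (4.63e-04), Nr4a1 -1.16 (0.0376) and Bag4 1.18 (3.9e-04). Matrix, immune and proliferation genes gave Acta2 -1.75 (0.00399), Thbs1 -1.46 (8.92e-04), Ccl2 -0.72 (0.0238), Id3 -1.72 (0.00186), Timd4 0.65 (0.0472), Mki67 -0.84 (0.0135), Igkv1-110 -1.21 (0.0318) and Hamp -2.01 (0.00295). In NC sham Acta2, Ccl2, Mki67 and Nr4a1 lay well below the pseudocount of 1 FPKM and had little room to fall there. Values for detoxification, amino acid and transport genes were Gsta1 -2.08 (8.92e-04), Gsta2 -1.06 (0.0359), Mgst3 -1.08 (3.9e-04), Mt1 -2.30 (0.0306), Cyp3a13 0.67 (0.0193), Slco1a1 0.90 (0.0249), Mat1a 1.08 (0.0191), Cps1 1.02 (0.0193), Slc23a2 1.31 (3.9e-04) and Slc25a32 1.04 (3.9e-04). The remaining genes were Rnf125 2.62 (0.00399), Rgs16 2.66 (0.0285), Hist1h1c -1.07 (0.0354), Tbc1d8 0.87 (0.0191), Ppm1k 1.56 (2.54e-04), Dnmbp 1.33 (2.54e-04), Crebrf 1.22 (4.08e-04), Jmy 0.86 (3.9e-04), Zfp871 0.96 (4.63e-04), mt-Ti -1.49 (0.0404), mt-Nd1 -0.67 (0.00771), AC147560.1 4.47 (0.0464) and AC153546.1 -0.70 (0.0378). AC147560.1 was near 0 in some samples of both NC groups and not in others, so its difference is uncertain. In 15 lists the interaction passed camera and in none with an estimated correlation. Their median differences were fatty acid oxidation 0.63, cytochrome P450 0.49, glucose metabolism 0.48, bile acid 0.42, periportal 0.33, choline and methionine metabolism 0.29, cholesterol synthesis 0.14 and lipid droplet 0.13 on the higher side, and cell cycle -0.71, immediate early -0.62, cytokines -0.39, mitochondrially encoded transcripts -0.30, interferon response -0.30, NRF2 -0.26 and extracellular matrix -0.25 on the lower. How far low levels on NC limited falls of the lower lists there was not tested.

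Heat shock genes were lower after RIC on CDAHFD, where 20 of 25 tested fell (score difference -1.03, exact permutation p = 0.00794, the smallest possible; 0.0454 adjusted over 40 score tests), and 5 of them fell on NC, where the score did not pass after adjustment (-0.308, exact permutation p = 0.0397, 0.127 adjusted) and limma's camera gave p = 9.25e-06 at the preset correlation and 0.107 with an estimated one. A difference in scale between samples was argued against, since 19 of the 20 and 4 of the 5 still passed as lower under median-ratio scaling. In sham mice CDAHFD had raised 17 of the 25 heat shock genes and lowered 0, where 6762 of all 10577 tested genes were called higher. That comparison shares the CDAHFD sham samples with the one for RIC on CDAHFD. Stress of handling that also raises immediate early genes stays open on CDAHFD, where the immediate early score was lower after RIC by a difference of -0.601 (exact permutation p = 0.00794, 0.0454 adjusted). It cannot be told apart on NC, where the heat shock score minus the immediate early score differed by -0.267 (exact permutation p = 0.175, 0.279 adjusted). A candidate explanation is that RIC itself lowers chaperone expression, which these samples do not separate from gentler handling, warmth or harvest order of the conditioned mice.

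G6pc, Igfbp1, Pdk4, Ppargc1a and Txnip were higher and Angptl8 lower after RIC on CDAHFD, a set that resembles fasting. In sham mice CDAHFD had lowered G6pc, Igfbp1 and Txnip and raised Angptl8, while Pdk4 and Ppargc1a were not called there. For the genes called there, RIC thus ran opposite to the diet, and both comparisons share the CDAHFD sham samples. The score of 15 other fasting-induced genes did not pass on CDAHFD (difference 0.294, exact permutation p = 0.0556, 0.139 adjusted) and was lower on NC (-0.311, exact permutation p = 0.00794, 0.0454 adjusted), which did not hold under median-ratio scaling (-0.245, exact permutation p = 0.0238, 0.0952 adjusted). CDAHFD sham samples 2 and 5 as the source were argued against, since 6 of 6 genes passed in the same direction without them, with G6pc at 1.35 instead of 2.13. Less feeding before harvest cannot be told apart, because feeding-induced genes without Angptl8 differed by -0.164 (exact permutation p = 0.357, 0.461 adjusted), nor can another harvest time, because the median absolute difference of 15 clock genes was 0.242 against 0.215 for all genes and 0.64 between the diets, although limma's fry gave the clock list a mixed p of 3.33e-08. RIC may act on hepatic glucose and lipid handling in a diet-dependent way, but feeding state and harvest time were not given in the sources used here.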

How the results depend on the processing

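The fit without CDAHFD sham samples 2 and 5 was chosen after the data were seen, and the other alternatives before the data were examined. Of 1895 values of named genes under an alternative, 1775 kept direction and side of the threshold, 116 no longer passed, 3 newly passed and 1 reversed. Of 1502 list values the numbers were 1359, 116, 25 and 2. Leaving out single samples, 1789 of 1973 gene values held, 180 were lost and 4 gained. For lists 1504 of 1584 values held, 43 were lost and 37 gained, and none reversed in either. Cpt1a turned to -0.28 for CDAHFD in sham mice under median-ratio scaling, where the median of all genes moves from 0.45 to 0.00. Under quantile normalization 2 lists turned upward for CDAHFD in sham mice. The lipoprotein median lay 0.20 above that of all genes and did not pass camera (adjusted p = 0.573). The acute phase median lay 1.13 above it and passed (adjusted p = 0.00303). The cause was not tested. With no filter more genes were tested, and 12361 were called for CDAHFD in sham mice and 48 for RIC on NC. With a mean of at least 5 FPKM fewer genes were tested, and the counts were 3562 for CDAHFD in sham mice, 1480 for RIC on CDAHFD, 3401 for CDAHFD in RIC mice, 386 for the interaction and 6 lists for RIC on NC. Fitting only the groups compared, with fewer samples for the spread, gave 1868 genes for RIC on CDAHFD and 46 for RIC on NC. For RIC on NC, quantile normalization gave 59 genes and array weights 401, and the cause was not tested. The opposite share of RIC and diet effects was 63.8% with a common sum. Without CDAHFD sham samples 2 and 5 the interaction count was 1266; the cause was not tested. With an estimated correlation 7 lists passed for CDAHFD in sham mice, 0 for RIC on CDAHFD, 0 for RIC on NC and 0 for the interaction, where the preset correlation of 0.01 gave 24, 11, 10 and 15. Fewer pass because all 33 lists have a higher estimated correlation. Leaving out 1 sample at a time, counts ran from 7587 to 7795 for CDAHFD in sham mice, 2073 to 3271 for RIC on CDAHFD, 13 (without NC sham 2) to 184 (without NC sham 4) for RIC on NC, 6877 to 7317 for CDAHFD in RIC mice and 438 (without NC sham 2) to 1042 (without CDAHFD sham 2) for the interaction. The opposite share ran from 71% to 78.2%. Passing lists ran from 23 to 24 for CDAHFD in sham mice, 8 to 15 for RIC on CDAHFD, 6 to 11 for RIC on NC and 14 to 17 for the interaction. With the replicate number as a block, the counts were 7857, 2547, 79, 7450 and 600 in the order of the report, and the opposite share was 73.1%. Correlations of the deviations of same-numbered samples ran from -0.174 to 0.176. Between NC RIC and CDAHFD sham 4 of 5 samples correlated best with their own number, and in other pairs of groups 0 to 2. The numbers are not read as a pairing, but a factor shared between NC RIC and CDAHFD sham is not excluded. Depth limits low genes: at the mean depth, 1 read in a 2 kb gene is 0.0254 FPKM, so levels near that value cannot be told from 0.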

Other observations

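Tests of scale, of other cell types and of the covariance under other splits were chosen after the results were seen, and the tests of shared samples and of other splits for counts before. Further lists moved with the diet in sham mice. Of 21 lysosome and autophagy genes 18 rose and 2 fell (median 1.13, adjusted p = 0.0109, and adjusted p = 0.319 with an estimated correlation), and of 6 red blood cell markers 4 fell and 1 rose (median -0.93, adjusted p = 8.49e-04, and adjusted p = 0.179 with an estimated correlation). In ER stress 5 of 20 genes rose and 7 fell, with a median of -0.16, a mean of 0.07 and a test below other genes (adjusted p = 9.03e-04, and adjusted p = 0.269 with an estimated correlation). Of 15 mitochondrially encoded transcripts 8 fell and 3 rose (median -0.24, adjusted p = 5.1e-05, and adjusted p = 0.269 with an estimated correlation). Pericentral genes went both ways, 6 of 16 up and 6 down, with a median of 0.15, a mean of -0.03 and a test below other genes (adjusted p = 0.00936, and adjusted p = 0.179 with an estimated correlation). Clock genes (7 of 15 rose, 3 fell, adjusted p = 0.176), p53 targets (11 of 16 rose, 1 fell, 0.568), hypoxia genes (6 of 12 rose, 2 fell, 0.749) and oxidative phosphorylation (14 of 24 rose, 1 fell, 0.485) did not pass.

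Fixed genes below the expression filter were compared by exact permutation tests with adjustment over 8 tests. The orphan receptor gene Nr4a3 was at 0.334 ± 0.0983 FPKM in CDAHFD sham, 0.00887 ± 0.0127 in NC sham and 0.0754 ± 0.0411 in CDAHFD RIC. Both differences from CDAHFD sham had an exact permutation p of 0.00794 (0.0159 adjusted), the smallest possible, and NC RIC did not differ from NC sham by the exact test (p = 0.365). Tnf, an inflammatory cytokine, was at 1.12 ± 0.355 FPKM in CDAHFD sham against 0.0467 ± 0.0767 in NC sham (exact p = 0.00794, 0.0159 adjusted) and at 1.03 ± 0.371 in CDAHFD RIC (exact p = 0.698 against CDAHFD sham).

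Diet and RIC effects on CDAHFD ran in opposite directions across genes, with a covariance of -0.133. Of 100 splits of the 9 CDAHFD samples 1 matched it, the real one (lowest of the others -0.105). The size of the covariance also grows with that of the RIC differences, and the real split called the most genes, so it does not exclude chance alone. The correlation was -0.414, and the other splits reached -0.441. The opposite share of 74.9% was matched by 10 of 100 (up to 83.2%), so chance was not excluded for the correlation or the share. For the covariance, the shared CDAHFD sham samples were argued against as the whole source, since it stayed below 0 in all 20 splits of them (highest -0.0943). A difference in scale was argued against as well. With a common sum (-0.166), median-ratio scaling (-0.124) and quantile normalization (-0.13), 1 of 100 splits, the real one, gave as low a covariance. Those splits of the 9 samples carry the same limit of size. For the share, a difference in scale cannot be told apart, because it was 63.8%, 73.4% and 74.1% under these rescalings and up to 25 of 100 splits gave as high a share. A lower share of every cell type other than hepatocytes cannot be told apart, because 5 of 13 Kupffer cell markers rose after RIC (Adgre1, Cd163, Cd5l, Vsig4 and Timd4) and Nr1h3 and Id3 fell, but neither the Kupffer score (difference 0.229, exact permutation p = 0.198, 0.305 adjusted) nor the Kupffer minus stellate score (0.616, exact permutation p = 0.0476, 0.127 adjusted) passed, and the Adgre1 and Cd163 calls were lost without single samples. Whether RIC moves the CDAHFD liver part of the way back or changes the share of its cells stays open.

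Other splits of the same samples tested the counts, with 100 splits each and the real one included. As many genes were called in 1 split for CDAHFD in sham mice (7852, highest other 4230), 1 for RIC on CDAHFD (2886, highest other 2636), 1 for RIC on NC (125, highest other 11), 1 for CDAHFD in RIC mice (7435, highest other 6229) and 1 for the interaction (711, highest other 419). No other split that was drawn reached these counts. Not every possible split was drawn and no adjustment was made over these tests, so chance was made less likely but not excluded. As many lists passed in 4 splits for CDAHFD in sham mice (24, highest other 25). Another split thus gave more passing lists, and no adjustment was made over these tests, so chance was made less likely but not excluded. As many passed in 56 for RIC on CDAHFD (11, highest other 23), 26 for RIC on NC (10, highest other 19), 8 for CDAHFD in RIC mice (20, highest other 23) and 11 for the interaction (15, highest other 20), where chance was not excluded.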
